A study of Mus musculus with 4 samples.

How the data were processed

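CD4 cells of wild type and sanroque mice were compared, with 2 arrays per genotype; genotype and replicate number were taken from the sample titles. The deposited table holds 1 intensity per probe set and array on a linear scale, for 22690 probe sets of the MOE430A array, a chip type given per the file headers of the experiment information. The algorithm that summarised the probes and the background correction are not given in the sources used here. The deposited intensity values were never negative, and their trimmed means, taken from the 2% to the 98% percentile of each array, lay between 99.59 and 99.97, so the arrays had been scaled to a common mean before deposit. No further scaling was applied. Detection calls and cell-level scanner values were not used here.

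The experiment information also gave each array's hybridisation and scan day. Both number 1 arrays shared a day and both number 2 arrays shared another, so the replicate numbers pair the arrays by day. This was decided before the fits with and without the block were compared. Across probe sets the deviations from the genotype mean correlated between same-numbered arrays with 0.392, from 2 pairs. A wash protocol was recorded for day 1 alone. The label text does not say whether the arrays of a genotype hold RNA of separate mice, so p-values measure the spread between these arrays, which may be technical.

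Signals were analysed as log2(signal + 6), where 6 is the 20th percentile of all values, rounded; fold changes on this scale understate the change of dim probe sets. The 64 control probe sets and all probe sets whose mean over the 4 arrays lay below the 40th percentile (21.3) were left out, which left 13579. Gene symbols came from the platform's annotation, updated by gene identifier through a RefSeq gene table. There, 20393 probe sets had 1 symbol and 691 had several, and 1555 others apart from controls were not listed and stay unnamed. Probe sets with several symbols were counted but not named, except where marked as named after their values were seen.

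Sanroque was compared with wild type by limma (lmFit and eBayes with a variance trend, version 3.58.1, in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The design had no covariates. For gene lists each gene was represented by its brightest probe set past the filter. The 22 lists were T cell states (follicular helper, naive, activated or memory, regulatory, Th1, Th2, Th17, inhibitory receptors), T cell receptor signalling, Roquin target mRNAs, immediate early and stress genes, interferon response, cell cycle, glycolysis, oxidative phosphorylation, ribosomal proteins, MHC class II presentation, and markers of B cells, plasma cells, CD8 T or NK cells, myeloid cells, and red cells or platelets. They were written from general knowledge before the data were examined. The 20 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists. With an estimated correlation per list, camera called 0 of 20, with 6 at an unadjusted p under 0.05. Fry, whose p asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, called 8 of 20.

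Genes were named by a rule fixed before the data were examined. It took Rc3h1 and Cd4, then the 12 largest rises and 12 largest falls among named probe sets past the test whose genotypes did not overlap and whose sign was the same in both numbered pairs. It added up to 3 members of each list with the largest change among those that did not overlap, and Icos, Cxcr5, Pdcd1, Il21, Bcl6, Cd200, Foxp3 and Cd44; a further gene of the rule is not reported here. Other genes are marked as named after their values were seen.

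The fits were tested on simulated data for the same comparison, 10 sets of 13579 probe sets with 200 changed in each. Limma recovered 1.04%, 22.2% and 78% of changes of 0.5, 1 and 2 on the log2 scale, and 4.69% of its calls were false. With the block it recovered 1.19%, 26.1% and 81.1%, with 9.22% false. In 10 simulations over 7860 genes, camera with the preset correlation called a list of 20 genes shifted by 0.7 in 10, and 2 of 200 unshifted lists. With an estimated correlation it called the shifted list in 0 of 10. The simulated probe sets varied independently and without a day effect, so these rates do not cover lists whose genes vary together.

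Alternatives were quantile normalization, centring each array on its median, a pseudocount of 1 or 24, no filter or a filter at the 60th percentile, no variance trend, the day or the wording of the titles as a block, each array left out, limma's treat with a minimum change of 1.2-fold, and for lists also camera with an estimated correlation, fry and the mean of a gene's probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.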

Results

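RNA from CD4 cells of mice was measured on 4 Affymetrix MOE430A arrays, 2 of wild type mice and 2 of sanroque mice. Sanroque is a mutant line made by chemical mutagenesis with ENU, and its mutation lies in Rc3h1, which encodes the RNA-binding protein Roquin-1. The deposited signals covered 22690 probe sets per array. After 64 control probe sets and those with a mean signal under 21.3 were left out, 13579 probe sets were tested, and 12424 of them carried a single gene symbol for 7860 genes. The trimmed mean signal lay between 99.59 and 99.97 on the 4 arrays, and the median between 30.8 and 40.4. On the log2 scale the arrays correlated across probe sets, which are not independent replicates, with r = 0.9663 between the wild type arrays, 0.9625 between the sanroque arrays, and 0.9357 to 0.9608 between arrays of different genotype. Each array of a genotype shared its hybridisation and scan day with an array of the other genotype, so every difference could also be read within each of 2 days. The labels name C57BL/6 as the strain that was mutagenised. The experiment information of wild type array 2 carries the letters CBA, which the labels do not explain. Whether both genotypes share a strain background is not known, so an effect of strain cannot be told apart from the mutation. The number of arrays limits the precision of every value.

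The comparison of sanroque with wild type asked which transcripts differ in CD4 cells of the mutant. Icos, Pdcd1, Cxcr5 and Il21, genes of follicular helper T cells, were higher in sanroque. So were 8 of 26 genes of activated or memory T cells, Cd44 among them, 5 of 29 cell cycle genes, and 5 of 26 myeloid genes, led by Ngp. Of 25 immediate early and stress genes 11 were lower, with Fos falling from a signal of 2681 ± 406 (SD, n = 2) in wild type to 90.35 ± 13.2 (SD, n = 2) in sanroque. The camera calls of these lists did not hold with an estimated correlation (adjusted p = 0.081 to 0.12). Cd4 itself was level, at 573.4 ± 56.7 in wild type and 578 ± 11.1 in sanroque (SD, n = 2 each), with a log2 fold change of 0.01 (adjusted p = 0.991). In all, 144 probe sets passed the limma test at an adjusted p of 0.05, 91 higher and 53 lower in sanroque, and they carried the symbols of 102 genes. Without sanroque array 2 the excess of higher calls was gone, with 52 of 105 higher. With the hybridisation day as a block the count was 852, of which 488 were higher, and all 144 were among them. All 144 had the same sign on both days, and the smallest of their changes within a day was 0.717 on the log2 scale. They were selected on these same arrays, which favours an equal sign, so this is no independent replication. No probe set could be named for Rc3h1, so it is not analysed here.

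**Figure D1:**
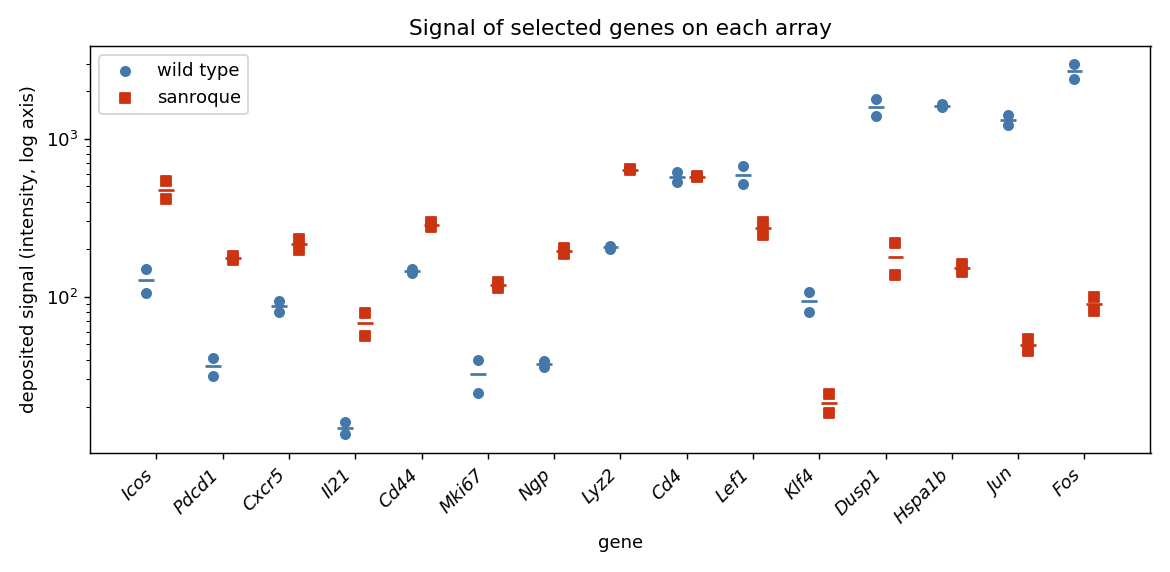
Deposited signal (intensity, log axis) of 15 genes on each array, with wild type arrays as blue circles, sanroque arrays as red squares and the mean of each genotype as a bar. Icos, Pdcd1, Cxcr5, Il21, Cd44, Mki67, Ngp and Lyz2 lay higher on both sanroque arrays, Lef1, Klf4, Dusp1, Hspa1b, Jun and Fos lower, and Cd4 did not separate the genotypes.

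Of 15 measured genes on the list for follicular helper T cells, the helpers of B cells in germinal centres, 5 rose and none fell, and 10 did not pass the test. Adjusted over the list alone, 9 rose, and with the day as a block 8 rose. The inhibitory receptor Pdcd1 rose from 36.25 ± 6.72 to 175.6 ± 6.43 (SD, n = 2 each), a log2 fold change of 2.11 with a standard error of 0.22 (adjusted p = 0.000797). The costimulatory receptor Icos rose from 127.3 ± 30.7 to 478.2 ± 85.7 (log2 fold change 1.87, standard error 0.215, adjusted p = 0.00143), by 1.81 on day 1 and 1.92 on day 2. The chemokine receptor Cxcr5 rose by 1.24 (adjusted p = 0.0133) and the cytokine Il21 by 1.82 (adjusted p = 0.0307). Sostdc1 rose by 2.90 (adjusted p = 0.0134) from a wild type signal of 3.5 ± 1.56, near the low end of the table. The transcription factor Bcl6 had a log2 fold change of 0.71 and did not pass (adjusted p = 0.423). Cd200 had 0.82 and did not pass either (adjusted p = 0.293), although it did with the day as a block (0.0326). Pdcd1 passed under every setting tried. Icos did not without the variance trend (adjusted p = 0.0635), nor did Cxcr5 (0.132) or Il21 (0.0507). Without the filter, Cxcr5 (0.0601), Il21 (0.168) and Sostdc1 (0.0527) did not pass. Il21 did not pass without sanroque array 1 (0.259) or 2 (0.0649), nor did Sostdc1 (0.089 and 0.102). As a group the list was higher than other genes by camera (adjusted p = 1.3e-12; adjusted p = 0.081 with an estimated correlation), with a median log2 change of 0.76.

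Among 26 measured genes of activated or memory T cells, 8 rose, none fell and 18 did not pass. Adjusted over the list alone, 17 rose and 1 fell, and with the day as a block 16 rose and 2 fell. Cd44, the adhesion receptor that marks antigen-experienced T cells, rose by 0.95 (adjusted p = 0.0307), Anxa2 by 1.17 (adjusted p = 0.0142) and Lgals3 by 1.11 (adjusted p = 0.0434). Another Cd44 probe set had 0.57 and did not pass (limma adjusted p = 0.607). Without the filter, Cd44 (0.0812), Anxa2 (0.0582) and Lgals3 (0.165) did not pass. The same held without the variance trend (0.209, 0.137 and 0.209). Cd44 did not pass with each array centred on its median (adjusted p = 0.241) or without sanroque array 1 (0.0684) or 2 (0.142); without sanroque array 2, Anxa2 (0.0719) and Lgals3 (0.246) did not either. Lgals3 also failed under quantile normalization (0.071), with median centring (0.0708) and without wild type array 2 (0.0561). The list was called higher (adjusted p = 2.4e-15; adjusted p = 0.081 with an estimated correlation). Of 10 inhibitory receptor genes 2 rose, Pdcd1 and the ectonucleotidase Nt5e (1.61, adjusted p = 0.0145), 4 rose adjusted over the list alone, and 4 rose with the day as a block. Lag3 had a log2 fold change of 1.72 and did not pass over all probe sets (adjusted p = 0.122), but did with the block (0.00159) and adjusted over the list alone (0.00621). That list was called higher too (adjusted p = 0.00033; adjusted p = 0.15 with an estimated correlation). Of 15 regulatory T cell genes 2 rose, Nrp1 by 1.21 (adjusted p = 0.0246) and Izumo1r by 1.00 (adjusted p = 0.0172), against 7 adjusted over the list alone and 7 with the block. Without sanroque array 2 Nt5e (0.101) and Izumo1r (0.0957) did not pass, nor did Izumo1r with median centring (0.294). Nrp1 did not pass without sanroque array 1 (0.0771) or under quantile normalization (0.0507). Foxp3, their lineage factor, had 0.64 and did not pass (adjusted p = 0.468). The list was called higher (adjusted p = 1.9e-07; adjusted p = 0.15 with an estimated correlation and 0.052 by fry).

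Of 12 Th1 genes 2 rose, the chemokine receptor Cxcr3 (1.07) and the chemokine Ccl5 (0.98), both named after their values were seen. Adjusted over the list alone 5 rose and 2 fell, Ifng and Runx3; with the block 5 rose and 2 fell, Il18r1 and Runx3. Members went both ways, with Eomes at 1.25 (adjusted p = 0.0782, 0.00095 with the block) and Runx3 at -1.20 (adjusted p = 0.422, 0.042 with the block). The list was called higher (adjusted p = 0.035; adjusted p = 0.34 with an estimated correlation), and that call was lost under quantile normalization (adjusted p = 0.085) and with each array centred on its median (adjusted p = 0.056), and without array 1 of sanroque (0.057) or wild type (0.072). It was also lost without the filter (0.37), without the variance trend (0.14) and by fry (0.15). Only 4 genes of the Th2 list and 3 of the Th17 list were measured, too few for a list test, and none of them passed. Adjusted over the list alone 0 Th2 and 3 Th17 genes rose, and 2 Th17 genes rose with the block, among them Ahr (0.92, adjusted p = 0.254, 0.0256 with the block). Of 14 naive T cell genes 1 fell and 13 did not pass; 1 fell adjusted over the list alone and 2 with the block. The transcription factor Lef1 fell from 595.3 ± 111 to 272.8 ± 36 (SD, n = 2 each; adjusted p = 0.0231), and did not pass with median centring (0.078) or without sanroque array 1 (0.1). Ccr7, a lymph node homing receptor, had -0.47 (adjusted p = 0.4, 0.0375 with the block). The naive list was called lower with a median of only -0.0722 (adjusted p = 0.033; adjusted p = 0.44 with an estimated correlation). Quantile normalization (adjusted p = 0.18) and median centring (adjusted p = 0.17) ended that call, as did leaving out sanroque array 1 (0.3) or wild type array 2 (0.23). So did the filter at the 60th percentile (0.062), no variance trend (0.053), the wording of the titles as a block (0.059) and fry (0.21).

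Genes of the immediate early and stress list, which respond within minutes to stimulation or to cell stress, were lower in sanroque as a list. Of 25 measured, 11 fell, 1 rose and 13 did not pass; adjusted over the list alone, 19 fell and 2 rose, and with the day as a block 19 fell and 1 rose. Fos fell by 4.80 on the log2 scale (standard error 0.188, adjusted p = 5.58e-07), with -4.79 on day 1 and -4.81 on day 2. Jun fell by 4.58 (adjusted p = 5.58e-07), from 1322 ± 146 to 49.65 ± 6.01 (SD, n = 2 each). The heat shock genes Hspa1a and Hspa1b fell, with log2 fold changes of -3.42 and -3.37, as did the phosphatase gene Dusp1 (-3.14), Ppp1r15a (-2.80) and Junb (-2.76). Outside the list, Tnfaip3, an inhibitor of NF-kB signalling, fell by 3.18, and Rgs2 (-2.28), Klf4 (-1.87) and the linker histone gene H1f2 (-1.76) fell too. Egr2, a transcription factor induced through the T cell receptor, went the other way and rose by 1.17 (adjusted p = 0.0317), although its other probe set had -0.34 and it did not pass without sanroque array 1 (adjusted p = 0.182) or under quantile normalization (0.0612). Fos, Jun, Hspa1a, Hspa1b, Dusp1, Ppp1r15a, Junb, Tnfaip3 and Rgs2 passed under every setting tried. H1f2 did not pass without sanroque array 2 (adjusted p = 0.0899) or wild type array 1 (0.0807). The list was called lower (adjusted p = 3.8e-33; adjusted p = 0.081 with an estimated correlation), with a median of -0.949, of -0.891 on day 1 and of -0.924 on day 2.

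**Figure D2:**
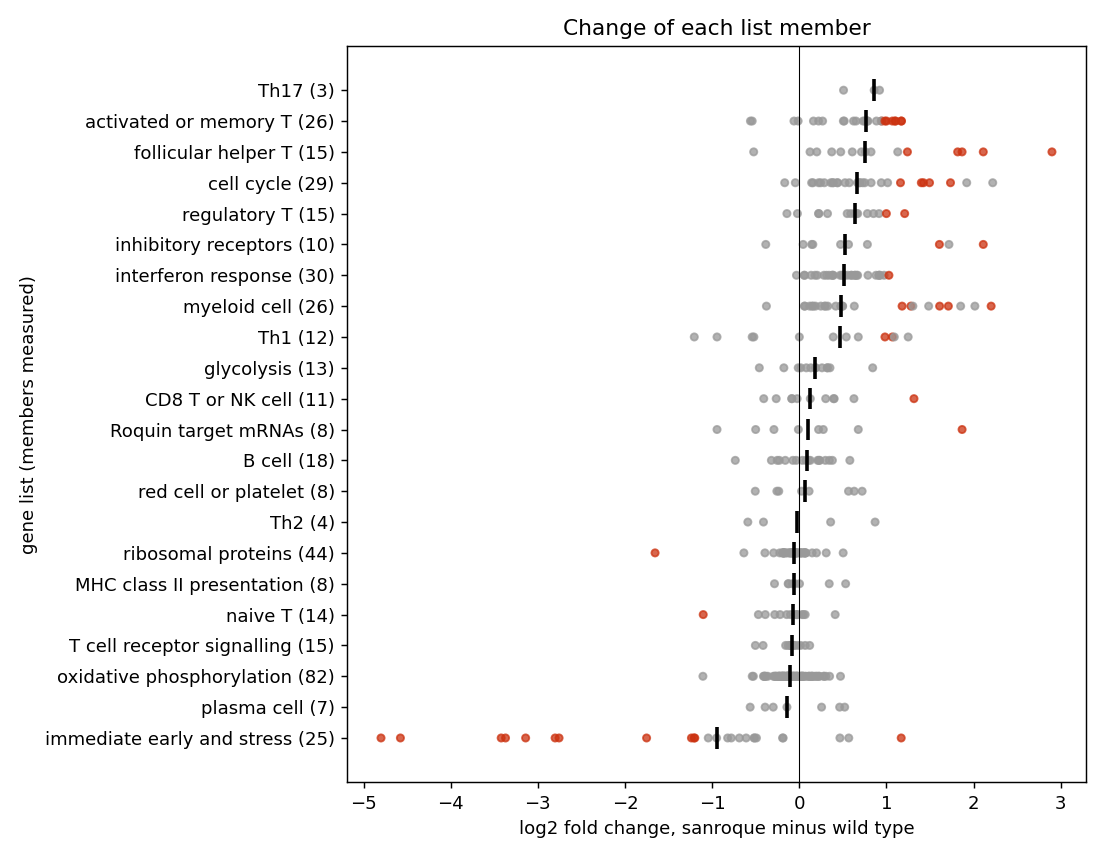
Log2 fold change (sanroque minus wild type) of each measured member of the 22 gene lists, with members past the test in red, others in grey and the list median as a black bar. The immediate early and stress list has the lowest median, -0.949, and the follicular helper list reaches 2.90.

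Of 29 cell cycle genes 5 rose, none fell and 24 did not pass, against 11 that rose adjusted over the list alone and 11 with the block. Mki67, a proliferation marker, rose by 1.74 (adjusted p = 0.0103), but did not pass without the filter (0.0872) or the variance trend (0.0781); the others, named after their values were seen, were Rrm2, Top2a (1.40), Nusap1 (1.43) and Ube2c (1.16). The list was called higher (adjusted p = 9.4e-14; adjusted p = 0.12 with an estimated correlation). Of 30 interferon response genes only Iigp1, an interferon-inducible GTPase, rose (1.03, adjusted p = 0.0209), but 29 had a positive change, and 13 rose adjusted over the list alone and 14 with the block. Iigp1 did not pass without sanroque array 2 (adjusted p = 0.13) or with each array centred on its median (0.263). Oasl2 had 0.97 (adjusted p = 0.191, 0.00684 with the block). The median of this list was 0.512 (adjusted p = 3.9e-14; adjusted p = 0.15 with an estimated correlation). No gene of 82 in oxidative phosphorylation passed, 0 adjusted over the list alone, and 2 fell with the block. Its median was -0.105, and the call as lower (adjusted p = 0.01; adjusted p = 0.71 with an estimated correlation) ended under quantile normalization (adjusted p = 0.21), by fry (0.72) and without sanroque array 1 (0.91). Without wild type array 2 it ended too, and the list's mean turned from -0.09 to 0.0471. The mean was also above 0 without sanroque array 1, at 0.00504.

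Lists of markers of other cells were tested 1 list at a time, and differences between them were not tested. Some such markers were bright in both genotypes. A probe set shared by haemoglobin genes, outside the lists, read 5910.7 to 8780.2 across the arrays. Cd74 had 1642 in wild type and 1593 in sanroque, above the 573.4 and 578 of Cd4. Both were named after their values were seen. These values leave open how pure the CD4 cells were. Of 26 myeloid genes 5 rose, all of them genes of neutrophils or lysozyme genes, and 21 did not pass; 8 rose adjusted over the list alone and 10 with the block. Ngp, a neutrophil granule protein gene, rose by 2.20 (adjusted p = 0.000329), from 37.7 ± 2.26 to 195.1 ± 12 (SD, n = 2 each). The lysozyme genes Lyz1 and Lyz2 rose by 1.71 and 1.61, and S100a8 and S100a9, which encode calprotectin, by 1.28 and 1.18; these were named after their values were seen. The list was called higher (adjusted p = 1.5e-11; adjusted p = 0.081 with an estimated correlation). None of 18 B cell, 7 plasma cell or 8 measured red cell and platelet genes passed by its brightest probe set. Their camera adjusted list p were 0.76, 0.57 and 0.16 (0.78, 0.71 and 0.44 with an estimated correlation). The plasma cell list had 14 genes, of which 5 had no probe set that named them alone and 2 lay below the filter. Ighg1, Ighg2b and Ighg2c were among those not measured, and probe sets with several symbols were not used for lists. The plasma cell result therefore does not cover these immunoglobulin genes. The B cell list holds Ighm by its brightest probe set (-0.25), although 4 of 8 measured Ighm probe sets rose, by up to 4.02. The red cell and platelet list was called higher with the filter at the 60th percentile (0.018) and without wild type array 1 (0.046). Adjusted over the list alone none of the B cell or plasma cell genes passed, and 3 of the red cell and platelet list rose, as 3 did with the block. With the block 1 B cell gene and 1 plasma cell gene fell. Of 11 genes of CD8 T or NK cells 1 rose, also adjusted over the list alone, the granzyme gene Gzmk (1.32, adjusted p = 0.0462; list adjusted p = 0.28), which did not pass without sanroque array 1 (0.125) or 2 (0.132) or wild type array 2 (0.116). For MHC class II presentation none of 8 genes passed, 0 adjusted over the list alone. Its mean was 0.0274 and its median -0.0636, camera placed it lower (adjusted p = 0.76) and fry higher (adjusted p = 0.72).

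Further lists were not called by camera in the main fit, nor with an estimated correlation. There the adjusted p was 0.6 for T cell receptor signalling, 0.58 for Roquin targets, 0.54 for glycolysis and 0.72 for ribosomal proteins. Of 15 T cell receptor signalling genes none passed, 0 adjusted over the list alone (list adjusted p = 0.12), and Cd3g had -0.10. Without sanroque array 2 (0.041) or wild type array 1 (0.014) that list was called lower. Of 8 measured mRNAs known as Roquin targets only Icos rose, also adjusted over the list alone (list adjusted p = 0.37 by camera), while fry called that list higher (adjusted p = 0.043), with 4 of its genes above 0 and 4 below. Camera called it higher with the filter at the 60th percentile (0.018). Of its genes, Ifng had -0.94 (adjusted p = 0.38) and Tnf 0.68 (adjusted p = 0.348, 0.0379 with the block). With the block 2 Roquin target genes rose. Of 13 glycolysis genes none passed, 0 adjusted over the list alone, and 1 fell with the block (list adjusted p = 0.28). Of 44 ribosomal protein genes 1 fell, Rps27 (-1.65, adjusted p = 0.0253), also adjusted over the list alone, and 2 fell with the block. Rps27 did not pass under quantile normalization (adjusted p = 0.0504), without the filter (0.147), without the variance trend (0.215) or without sanroque array 2 (0.0503). That list had an adjusted p of 0.061, and was called lower with the day as a block (0.04), with the mean of a gene's probe sets and without sanroque array 2 (0.026) or wild type array 1 (1.6e-05).

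For several of the largest rises, another probe set of the same gene moved far less. Rpgrip1 rose by 4.02 (adjusted p = 3.72e-06), while its other probe set had 0.29. Trim34a rose by 3.82 and its other probe set had -0.47; Ifi209, an interferon-inducible gene, rose by 3.68 against 0.72. Psmd6, a proteasome subunit gene, rose by 2.20 against 0.10. Of 8 measured Ighm probe sets 4 rose, by 4.02, 2.30, 1.60 and 1.29. The first went from 11.2 ± 3.68 to 272.5 ± 46.5 (SD, n = 2 each), while the brightest Ighm probe sets, with 1653.7 and 2334.6 on wild type array 1, had 0.01 and -0.25. Trim12a rose from 2.1 ± 2.12, near the low end of the table, to 121 ± 1.13 (SD, n = 2 each). The remaining large rises were Plagl1 (2.45), Bpifa2 (2.11) and Cdk5rap1 (2.00); Plagl1 did not pass without sanroque array 1 (adjusted p = 0.248) or 2 (0.0771). In the other direction H2-Ea, an MHC class II gene, fell by 2.02 (adjusted p = 0.0352), and its other measured probe set had -0.58 (adjusted p = 0.558). H2-Ea did not pass under quantile normalization (adjusted p = 0.11) or without wild type array 2 (0.0819).

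**Figure D3:**
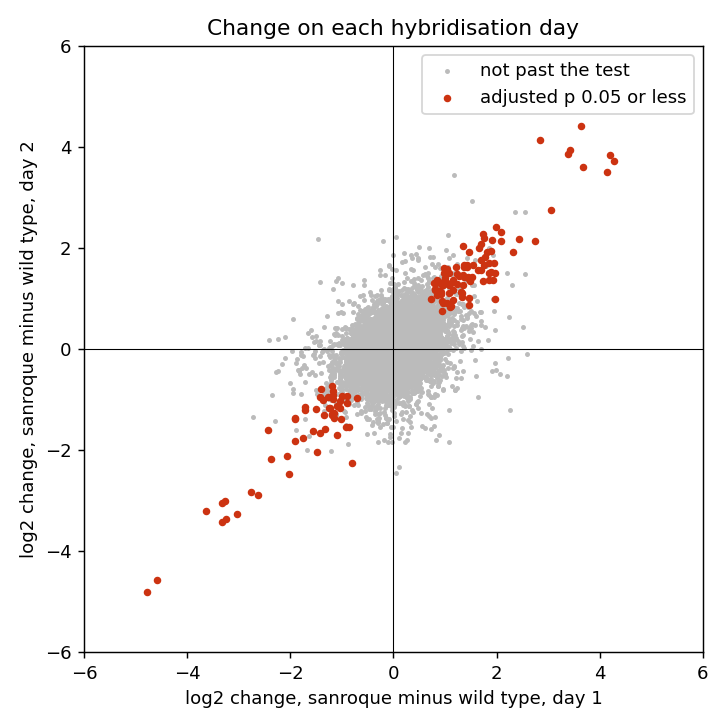
Log2 change (sanroque minus wild type) of each of 13579 probe sets on hybridisation day 1 (x axis) against day 2 (y axis), with the 144 past the limma test in red and the rest in grey. All 144 lie in the quadrants where both days have the same sign, which their selection on these same arrays favours.

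Groups of 2 arrays allow an exact permutation test no two-sided p under 0.333, so all p-values rest on limma's variance model, and nothing in the labels says that the arrays hold RNA of separate mice. On 5255 probe sets, 38.7% of those tested, the genotypes did not overlap. Chance gives 33.3% for exchangeable arrays, and the shared days make that value approximate. Of these, 290 differed at least 2-fold, 183 higher and 107 lower, a split that was 152 higher and 138 lower with each array centred on its median, and 178 higher and 183 lower without sanroque array 1. The count of 144 was 356 without wild type array 1, 56 without the filter on low signals and 47 without the trend in the variance model, where 20 and 17 of 39 calls of named genes were lost. On wild type array 2 the control probe set for the 5′ end of 18S ribosomal RNA read 1992.8, against 35.4 to 107.4 on the other arrays, and without that array 172 probe sets passed.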

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

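Leaving out arrays and median centring were chosen for the 2-fold count only after the data were seen; all other settings were planned. The count of 144 probe sets past the test was 852 with the replicate block (the hybridisation day), which shared all 144. It was 56 without the filter, where more probe sets were tested, 47 without a variance trend and 80 with a minimum change of 1.2-fold, and it ranged from 105 to 356 with each array left out, where the lone array of a genotype is assumed to vary like the others. The 356 came without wild type array 1. Of the 105 without sanroque array 2, 52 were higher. The minimum change is stricter by construction; for the drop without a trend and for this rise the cause was not tested. Other settings gave 128 to 180. No call of the 144 reversed under any setting. Of the lists, 11 were called, and 0 with an estimated correlation. That setting called no shifted list in the simulation either, but the simulated genes were independent, so this does not settle the list calls. The block added ribosomal proteins and changed no other list call. The 290 probe sets that differed at least 2-fold without overlap were 139 with a pseudocount of 24, which shrinks dim changes, 656 without the filter, 147 with the filter at the 60th percentile, and 355 to 578 with arrays left out. Changes of sign were of values that had not passed the test, except the oxidative phosphorylation list. The Cd4 change was -0.0758 with median centring and -0.0851 to 0.11 with each array left out. List means with each array left out ranged from -0.227 to 0.0471 for oxidative phosphorylation and from -0.204 to 0.0194 for ribosomal proteins, both highest without wild type array 2. They ranged from -0.053 to 0.108 for MHC class II presentation and from 0.034 to 0.0575 for B cells, whose mean stayed positive while camera's direction turned. MHC class II presentation had a mean of 0.0465 with quantile normalization, and its mean of 0.0274 was placed higher by fry. The plasma cell mean of -0.0218 was 0.0799 with the mean of a gene's probe sets and ranged from -0.105 to 0.0612 with each array left out, above 0 without sanroque array 2 or wild type array 1. For these turns the cause was not tested. Among 1129 comparisons of a named gene with its value under another setting, 1013 kept side and direction, 71 lost the call, 42 gained it and 3 turned. Experiment day as a batch is identical to the replicate number and was not run apart. Detection calls were not used here, so no dim probe set was checked by them.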

Other observations

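The tests in this part were chosen only after the result was seen, apart from that of neutrophil markers outside the earlier lists, to which conditions were later added.

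Outside the lists, 3 probe sets of Socs3, an inhibitor of cytokine receptor signalling, rose together by 1.17, 1.36 and 1.21 on the log2 scale (limma, adjusted p = 0.0154, 0.00441 and 0.0176), higher on both sanroque arrays. Among the falls of the immediate early and stress list was Zfp36, which encodes a protein that destabilises mRNAs (-1.24, adjusted p = 0.00478). Its signal was 742 and 766.3 on the wild type arrays and 323.8 and 309.2 on the sanroque arrays. These genes were named after their values were seen.

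The first pattern is the 16 probe sets at least 4-fold higher in sanroque and past the test. Of their 11 named genes, 5 had another measured probe set, and in 80% of these, Rpgrip1, Trim34a, Ifi209 and Psmd6, every partner changed by under 25% as much, against 0 of 4 genes among equally large falls, while Ighm had 4 of 8 probe sets past the test. That disagreement was what prompted the idea, so it is no independent evidence that a sequence variant between the wild type and sanroque mice is read by single probe sets, which stays open, as does a transcript form read by a single probe set. The 0 among the falls depends on the limit of 25%, because H2-Ea lay just above it, with -0.58 for its other probe set against -2.02. For an interferon response as the whole source, the largest change on the interferon list was 1.03, by each gene's brightest probe set and with Trim and H2-Q genes aside. A second probe set of Iigp1 had 1.30. Both lay below 1.599, which is 50% of the pattern's median, so the measured list genes did not change by as much as the pattern. Of the list's 39 genes 30 were measured, and 7, which include Ly6a, had no probe set that named them alone. Some of the 16 probe sets carried no single symbol and could not be matched to the list. The pattern was selected for large changes and holds the interferon-inducible Ifi209, so this bound cannot decide the question. The labels name C57BL/6 as the mutagenised strain. The letters CBA in the experiment information of wild type array 2 also name an inbred strain. H2-Ea read 95.5 and 135.5 on wild type arrays 1 and 2, against 12.7 and 40.4 on the sanroque arrays. Among the 16, a probe set shared by H2-Q7 and H2-Q9, named after its values were seen, read 91 and 52.9 against 1013.6 and 853.7. These differences were present on both wild type arrays, not on array 2 alone. A strain difference between the genotypes could underlie part of the calls, these included, and was not tested.

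The second pattern is the fall of immediate early and heat shock genes, past the test for 11 of 25 on the list, Hspa1a and Hspa1b among them, and for 1 of 8 heat shock genes outside it, Dnajb4 (-1.32, adjusted p = 0.016), named after its value was seen. RNA degradation in the sanroque samples is argued against by the ratio of 3′ to 5′ actin control probe sets, which differed by 0.0774 on the log2 scale between the genotypes. For less recent antigen receptor stimulation the evidence was mixed, because receptor-induced genes had a median of 0.568 but ran from -1.04 to 1.17, with 6 of 9 above 0, and 5 of the 9 belong to the falling list. The other 4, Nfatc1, Il2ra, Tnfrsf9 and Irf4, were all positive with a median of 0.801. Nfatc1 and Tnfrsf9 are also on the activated or memory list and Il2ra on the regulatory list. Both lists were called higher, so these 4 cannot decide on recent stimulation. Among the 5 shared with the falling list, Nr4a1 had -0.78 and Nr4a2 -1.04 (limma adjusted p = 0.0828 and 0.397), while Egr2 rose. Apart from Egr2, these genes were named after their values were seen. A difference in handling between the genotypes cannot be told apart from the genotype, as no sample was handled both ways by its label; heat shock genes outside the list had a median of -0.325.

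The third pattern is a rise of neutrophil granule and lysozyme genes, 8 genes picked from the myeloid list after their values were seen, which were all positive with a median of 1.66 and of which 5 passed the test. A lower share of CD4 T cells was asked about through B cell genes, each by its brightest probe set. Their median was 0.0923 (quartiles -0.138 and 0.233), below 0.415, which is 25% of the granule median. Macrophage genes had 0.217. B cell genes thus showed no rise as a set. This cannot decide on the share of CD4 T cells, because neutrophils alone could lower it. The granule genes behind the bound were also picked after their values were seen. Whether there were more neutrophils in the sanroque preparations stays open: of 20 neutrophil markers outside the earlier lists 5 were measured, with wild type signals of 14.4 to 25.9, all positive with a median of 0.644 but none past the test, while the neutrophil genes Csf3r and Mpo of the myeloid list had 0.06 and 0.42 (adjusted p = 0.978 and 0.852). The median of 0.644 met the bound set beforehand for more neutrophils. The conditions that Csf3r and Mpo rise as well and that a marker pass the test were added after the values were seen. Lyz1 rose from 513.2 to 1679 and S100a8 from 205 to 505. Lysozyme is also made by macrophages. A selection of CD4 cells would remove neutrophils, and whether more neutrophils came with the mutation was not tested.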
